A study of Mus musculus with 3 samples.

How the data were processed

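LNC, a malignant B-1 cell line derived from a lymph node of a New Zealand Black mouse, was profiled on 3 arrays of the first version of the A array of the Affymetrix Murine Genome U74 set, 1 array per group. Per the labels, 1 group received an IL-10 antisense oligonucleotide at 20 µM, 1 received a scrambled oligonucleotide at 20 µM as a control for unspecific effects of oligonucleotides, and 1 was left untreated, with RNA taken at 24 h. Whether each array held RNA of 1 culture or a pool is not given in the sources used here.

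The authors deposited 1 table of probe set intensity values on a linear scale, with 12654 probe sets per array, of which 66 are Affymetrix controls. Between 24.8% and 28.0% of the deposited intensity values on an array are at or below 0, as a difference of perfect-match and mismatch probes gives. The mean of the deposited values after removal of the lowest and highest 2% is 1500 on each array, so each array had been scaled by the authors to this level. The software is not given in the sources used here.

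For the present comparisons, each array was scaled again to a common trimmed mean, with 2% removed from each end, over the 12588 probe sets that are not controls. The fixed plan was to set a floor at the 20th percentile of the pooled values. That percentile was -79.8, and the 10th percentile planned as an alternative was -282.8, and neither has a logarithm. The floor was therefore set to 2 robust standard deviations of the values below 0, which is 595.9, after the distribution of values had been seen and before any comparison was made. Values below the floor were set to it and log2 was taken. Probe sets whose mean log2 value over the 3 arrays was above the median of all probe sets were kept, which left 6127. This median was the floor itself, so a probe set was kept when any of its 3 values lay above the floor. A probe set could thus pass through a single array.

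Gene symbols came from the platform annotation. Exactly 1 symbol was listed for 10298 probe sets and several for 363, while 1949 probe sets other than controls were not listed and stayed unnamed. The gene identifiers of 10279 of the probe sets with 1 symbol matched the RefSeq gene table. No gene was named from a probe set with several symbols. No genome was given, so positions are not reported. Suffixes of a probe set identifier such as _s, _f, _r, _i and _g mark shared, family or reduced probe sets, which can bind transcripts of more than 1 gene. Some probe sets of the first version of this array are known to have been built on faulty sequence, and they were not identified here.

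With 1 array per group there is no replicate check, so no test was run and no p-value is given. Differences are log2 intensities of 1 array minus another, and a probe set was counted when it was at least 2-fold apart. As a yardstick of error, the 95th percentile of the absolute difference between the scrambled and untreated arrays was taken over the 300 probe sets nearest in mean level. This yardstick corresponds to 2.28-fold at an intensity of 1000, 1.32-fold at 8000 and 1.26-fold at 16000, and it includes any effect of the scrambled oligonucleotide. The number of arrays limits the precision of every value. Each count was set beside 100 simulated data sets, in which all 3 arrays were unchanged and scattered at each level as the scrambled and untreated arrays do. For these 2 arrays themselves the simulation gave a mean of 153 probe sets 2-fold apart, at most 180, where 190 were counted, so simulated counts run low. Where 2 comparisons share an array, the overlap of independent lists is given too, and part of any excess can come from the shared array.

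Before the data were examined, 34 gene lists and the rule for named genes were fixed. A gene was represented by its probe set of highest mean level. For the 32 lists with at least 5 members past the filter, the median difference was placed among 10000 random lists of the same size, matched on mean level in 20 bins. A list was counted as apart when its median lay outside the central 95% of random lists in the same direction against both controls. Random lists would give 0.33 such lists among the 32. These percentiles describe the 3 arrays and carry no p-value. Named genes had 1 symbol, lay past the filter and were above the floor on the 3 arrays. They are the 12 highest and 12 lowest in the array labelled antisense against both controls, ranked by the smaller difference, the 8 highest and 8 lowest with both oligonucleotides against untreated, the 4 highest and 4 lowest in the scrambled array against both others, and up to 4 members per list with the largest difference from the mean of the controls. Il10 and 16 genes fixed with it were to be given whatever their level, and 2 of these are not reported here. A fold against values at the floor was computed against the floor and is a lower bound.

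The counting was tested on 20 simulated data sets of 6127 probe sets, of which 200 were changed. At a log2 change of 1.0, 28.3% of the changed probe sets were called, at 1.5 it was 69.9% and at 2.5 it was 79.0%, and 0.61% of unchanged probe sets were called. For the lists, a shift of -0.35 added to the finished differences of 18 genes was recovered in 19 of 20 data sets. It was added after the floor, so genes near the floor were shifted in full, and recovery on real arrays can be lower. Of 600 unchanged lists, 2 were called. The unchanged lists were random genes, so this does not show how often lists of genes that vary together would be called. The alternatives were the values as deposited, quantile normalization, other floors, filters and fold thresholds, removal of probe sets with a suffix, the mean of a gene's probe sets and coarser matching. Scaling to bacterial spike-in controls, a floor of 4 robust standard deviations and removal of the brightest probe sets were added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, and quantile normalization was run in R 4.3.3 with limma 3.58.1.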

Results

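RNA of the malignant murine B-1 cell line LNC was measured on 3 arrays: 1 of cells given an IL-10 antisense oligonucleotide, 1 of cells given a scrambled oligonucleotide and 1 of untreated cells. IL-10 is a cytokine that malignant B-1 cells are known to make and to use for their own growth. The comparisons ask which transcripts differ when IL-10 is targeted, and which of these differ from cells given a control oligonucleotide. The share of probe sets above the noise floor was 42.1% on the array labelled antisense, 42.6% on the scrambled array and 42.0% on the untreated array. Differences are relative to the common level of each array. The 6 bacterial spike-in control probe sets that were not among the brightest were lower on the array labelled antisense, by a mean log2 difference of -0.63 against untreated and -0.51 against scrambled. Scaling to these controls would shift values above the floor by 0.63 and 0.51 in those comparisons and by 0.12 between the scrambled and untreated arrays.

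Il10, the targeted gene, was higher on the array labelled antisense than on both controls. Its probe set had an intensity of 13946 there, 5616 on the scrambled array and 5164 on the untreated array, which is 2.70-fold over untreated and 2.48-fold over scrambled. A second Il10 probe set among the array's controls read 6346, 3966 and 3391 on the same arrays, or 1.87-fold and 1.60-fold. These differences exceed the yardstick at those levels, and the direction is opposite to a loss of the targeted RNA. An antisense oligonucleotide can block translation without lowering the RNA, so the RNA level neither settles the label nor measures the IL-10 protein. The array is therefore called the array labelled antisense throughout, and each direction drawn from it below rests on that label.

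Among the other genes fixed with Il10, the cell-cycle inhibitor gene Cdkn1a was higher on the array labelled antisense. The brighter of its probe sets on the control arrays read 3050.1 against 1205 on the scrambled and 961 on the untreated array, with log2 differences of 1.34 and 1.67. Its second probe set read 3595 against 2 values below the floor, at least 6.03-fold higher. Bcl2, which restrains apoptosis, read 4423 against 2868 and 2770.0, with log2 differences of 0.63 against scrambled and 0.68 against untreated, the first within and the second slightly above the yardstick of 0.66. Cdc25c, a phosphatase that activates Cdk1 for entry into mitosis, read 1035 against 2050.4 and 2049, a log2 difference of -0.99 from either control. Its dimmer probe set differed by -0.52 against untreated and -0.14 against scrambled. Cdk1 itself differed by -0.34 against untreated and -0.27 against scrambled, the first slightly above and the second within the yardstick of 0.33 at its level. The cell-cycle inhibitor gene Cdkn1b differed by 0.00 and -0.02 in its probe set above the floor. Myc differed by 0.20 and 0.05, and Pax5, a B lineage transcription factor, by -0.11 and -0.27. Il10rb, a chain of the IL-10 receptor, read 4723 on the array labelled antisense, 4502 on the scrambled and 2714 on the untreated array. Jak1 differed by -0.34 against untreated and -0.03 against scrambled, and Stat3 by 0.10 and -0.45 in 1 probe set and by -0.06 and -0.26 in another. Tert, the catalytic subunit of telomerase, read 1449 on the array labelled antisense, 2299 on the scrambled and 799 on the untreated array, and the first value lay within the yardstick of either control. Il10ra, Tyk2 and Socs3 were at or below the floor on the 3 arrays, and Ccnb1 was not analysed here.

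Pim2 and Pim1 were among the genes higher on the array labelled antisense than on both controls. They encode serine/threonine kinases that promote survival downstream of cytokine receptors. Pim2 read 14958 against 3634 on the scrambled and 3351 on the untreated array, or 4.12-fold and 4.46-fold. Pim1 was 3.57-fold and 4.61-fold higher in 1 probe set, and a brighter probe set of Pim1 read 17982 against 7444 and 6134. Bag1, a co-chaperone that binds Bcl2, was 2.69-fold over scrambled and 3.06-fold over untreated. The calcium-regulated transcription factor gene Nfatc1 was 2.59-fold and 2.71-fold higher, and Prkca, a protein kinase C gene, 3.45-fold and 2.88-fold higher. Adgrd1, an adhesion receptor gene, and Epo, the erythropoietin gene, were higher by log2 differences of 1.34 or more against each control. Dda1, a component of ubiquitin ligase complexes, differed by 1.45 against untreated and 1.81 against scrambled in 1 probe set, by 0.18 or less in 2 others and by -0.82 and -0.72 in another. Ifna5, a type I interferon gene read by a family probe set, differed by 1.29 against untreated and 1.62 against scrambled. A family probe set assigned to the immunoglobulin heavy chain gene Ighm read 5746 against 1104 and 1023, a log2 difference of 2.38 and 2.49. Other Ighm probe sets went both ways: 1 read 25443 against 16004 and 13300.3, 1 read 75374 against 81918 and 80245, and 1 read 145519 against 183787 and 155216.

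The genes lower on the array labelled antisense than on both controls were mostly of modest level. Most of the 12 lowest read little above the floor of 595.9 on that array, from 609 for Cel to 754 for Serpinf1. Pfkm, a phosphofructokinase of glycolysis, read 664 against 2556 on the scrambled and 1875 on the untreated array. Timp1, an inhibitor of metalloproteinases, read 700.0 against 3001 and 1826, and Plat, the tissue plasminogen activator gene, read 1306 against 3733 and 3414. Necap2, an endocytic adaptor gene, differed by -1.43 against untreated and -1.97 against scrambled. Pxn, the gene of the focal adhesion adaptor paxillin, differed by -1.44 and -1.64, and Rasgrp2, an activator of Rap1, by -1.33 and -1.62. Stxbp2, which serves vesicle exocytosis, Cel, a lipase gene, Serpinf1, a secreted serpin gene, Plac8 and 2610001J05Rik were also among the 12 lowest, with differences of -1.31 to -1.90. Another probe set of Stxbp2 differed by -0.35 against untreated and -0.49 against scrambled. H2-Q5, a non-classical major histocompatibility gene, differed by -2.31 and -1.58 in a family probe set.

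In all, 83 probe sets were at least 2-fold higher on the array labelled antisense than on both controls and 65 were at least 2-fold lower, 56.1% of them higher. This balance turned with the processing, to 125 higher and 295 lower with the floor at the 40th percentile of values and to 512 higher and 19 lower with scaling to the spike-in controls. Simulated unchanged arrays, whose counts run low, gave a mean of 23 higher, at most 38, and a mean of 15.4 lower, at most 25. Independent lists would share 5.18 and 3.81. Of the 83, 63 exceeded the yardstick in both comparisons and 37 were above the floor on the 3 arrays. Of the 65, these numbers were 51 and 38. Where other probe sets of the same gene passed the filter, their mean went the same way for 11 of 15 higher probe sets, with a median of 0.67. Both probe sets of Pim1 and both of Cdkn1a were among the higher ones, so each of these was compared with another that was also counted. For the lower ones the mean of the others went the same way for 5 of 7, with a median of -0.13.

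**Figure D1:**
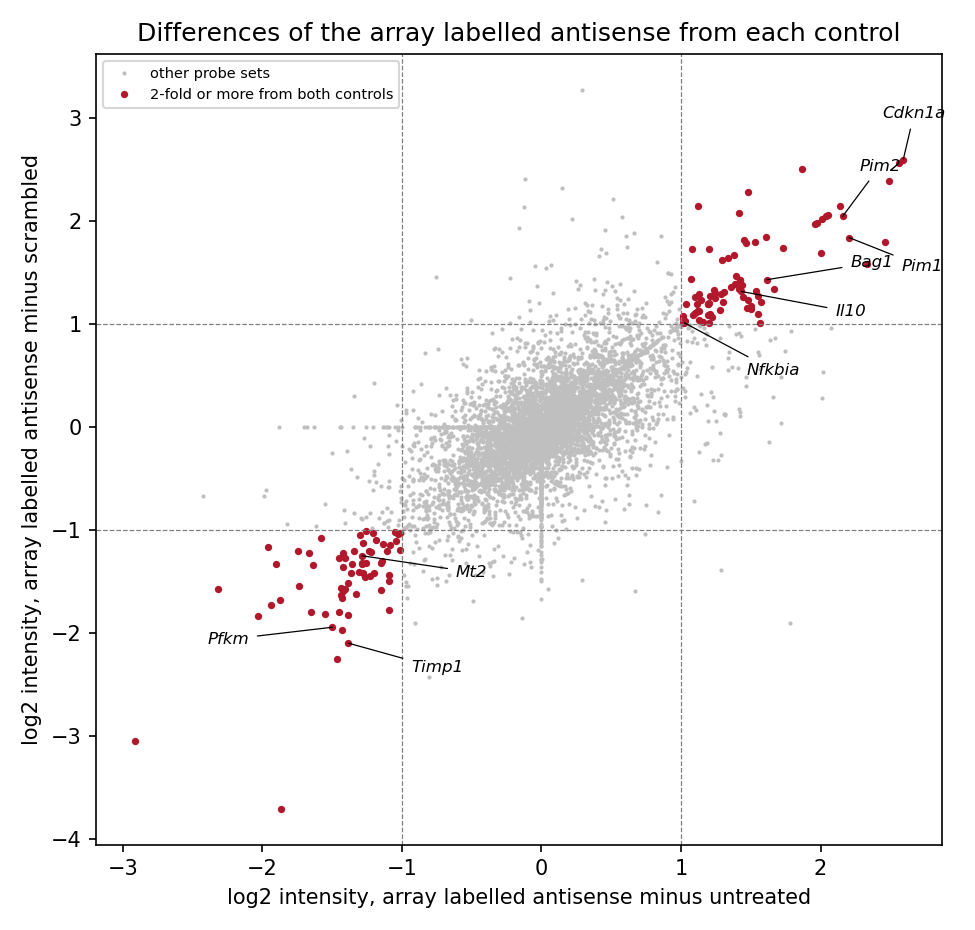
Log2 intensity differences of the array labelled antisense from the untreated array (horizontal axis) and from the scrambled array (vertical axis), 1 point per probe set past the filter. Red points are the 83 probe sets at least 2-fold higher and the 65 at least 2-fold lower than both controls, relative to the common level of each array. The points on the 0 lines are pairs of values that were both at the floor.

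Among the fixed gene lists, the list of genes that restrain apoptosis had a higher median on the array labelled antisense. The median of the 8 such genes past the filter differed by 0.61 against untreated and 0.59 against scrambled, at the 99.98th percentile of matched random lists in both, and by 0.03 between the controls. Of the 8, 5 were higher than both controls and 1 was lower. The lower one, Birc5, differed by -0.35 against untreated and -0.11 against scrambled. Mcl1, at -0.05 and 0.03, and Cflar, at 0.05 and -0.30, went different ways against the controls. Without the filter, over all 11 members on the array, the medians were 0.05 and 0.03 and the list was not apart, at percentiles of 90.2 and 90.5. Members left out by the filter had all values at the floor. Bag3 passed the filter only through the array labelled antisense, at 880 against 541 and 444, both below the floor. Besides Bag1 and Bcl2, Bcl2l1, which encodes Bcl-xL, differed by 1.34 and 0.72, the second within the yardstick of 0.82, and Birc2, an inhibitor of apoptosis, by 0.67 and 0.68, slightly above its yardstick of 0.64. The lists of p53 targets, NF-kB targets and genes that promote apoptosis were not apart from both controls. In the p53 list, 7 of 13 genes were higher than both controls and 5 lower, with medians of 0.27 and 0.27, at percentiles of 97.1 and 97.1. Between the controls its median was -0.22, at a percentile of 1.94. It includes Cdkn1a and the cyclin gene Ccng1, which differed by 1.57 and 1.01, the second within the yardstick of 1.23. In the NF-kB and TLR9 list, 11 of 20 genes were higher than both and 5 lower, with medians of 0.17 and 0.22. Nfkbia, the inhibitor of NF-kB that NF-kB itself induces, read 26784 against 13318 and 13171. Nfkbie, a relative of it, differed by 0.94 and 1.30, Traf2, an adaptor of tumour necrosis factor receptors, by 0.90 and 1.49, and Tnf by 0.83 and 0.91. Both Tnf differences and that of Nfkbie from untreated lay within the yardstick. In the list of genes that promote apoptosis, 5 of 13 were higher than both and 3 lower, with medians of -0.01 and 0.22. Bcl2l11, which encodes the BH3-only protein Bim, differed by 0.96 and 1.36 in 1 probe set and by -0.18 and -0.32 in another. In the list of CDK inhibitors, 3 genes passed the filter, too few for a median.

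Genes of cholesterol synthesis were lower on the array labelled antisense than on both controls. Of 18 measured, 16 were lower than both and 1 was higher, and the median differed by -0.33 against untreated and -0.51 against scrambled, at percentiles of 0.01 and 0.00. Srebf1, a transcription factor of lipid synthesis, read 3122 against 6009 on the scrambled and 5253 on the untreated array. Fdps, which makes farnesyl diphosphate, read 13909 against 25649 and 21339.6, and Fdft1, the squalene synthase gene, differed by -1.15 against untreated and -0.57 against scrambled. Tm7sf2, a sterol reductase gene, went the other way, by 0.86 and 0.46. The differences of Fdft1 and Tm7sf2 from scrambled lay within the yardstick. The median of this list was 0.18 higher on the scrambled than on the untreated array, at a percentile of 98.8. The controls themselves thus differed on this list, and by the same rule the scrambled array was apart from both others.

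B cell genes were also lower on the array labelled antisense. Of 27 genes of B cell identity, 14 were lower than both controls and 6 higher, with medians of -0.16 against untreated and -0.27 against scrambled at percentiles of 1.96 and 0.17. Ms4a1, which encodes CD20, read 31106 against 44803 and 44237, and Spib, an ETS transcription factor of B cells, read 8629 against 16871 and 15336. Ikzf1, the Ikaros gene, differed by -1.11 and -0.78, and Cd24a by -0.37 and -0.56. Of 19 genes of antigen presentation, 12 were lower than both and 2 higher, with medians of -0.21 and -0.24 at percentiles of 0.48 and 0.96. The class II chain gene H2-Aa read 16961 against 25041 and 23224, and Cd74, the invariant chain, read 63917 against 92660.4 and 81644. H2-Oa, a class II modulator, differed by -0.90 and -0.78, and Tapbp, the tapasin gene, by -0.57 and -0.33, the second within the yardstick. The B cell list was not apart without probe sets above an intensity of 50000, at a percentile of 4.04 against untreated, nor the antigen presentation list without suffixed probe sets, at 5.42 against scrambled.

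Of 17 genes of histones and chromatin, 10 were lower than both controls and 5 higher, with medians of -0.22 and -0.20 at percentiles of 0.295 and 2.09. H2ax, a histone variant of DNA repair, differed by -0.95 from either control, Hmgb2 by -0.77 and -0.73, and Ezh2, a histone methyltransferase gene, by -0.61 and -0.59. This list was apart in 3 of 11 alternative settings. Of 28 genes of G2/M progression, 17 were lower than both controls and 5 higher, with medians of -0.27 against untreated and -0.13 against scrambled at percentiles of 0.00 and 4.75, so the list was not apart from both, nor was it in any of the 11 alternative settings. The mitotic kinase gene Plk1 read 5698 against 9589 and 9815, and Cdc20, an activator of the anaphase-promoting complex, read 8215 against 13712 and 13382. Of 31 genes of DNA replication, 16 were lower than both and 6 higher, with medians of -0.13 and -0.05. The helicase subunit gene Mcm5 differed by -0.49 and -0.60. Of 27 proteasome genes, 17 were lower than both and 4 higher, with medians of -0.16 and -0.13 at percentiles of 0.18 and 4.32.

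In total, 5 of 32 lists were apart from both controls, where random lists would give 0.33. That number is for random genes and can be too low for lists of genes that vary together. By the same rule the scrambled array was apart from both others in the cholesterol list and in the list of ribosomal proteins. For ribosomal proteins the percentiles were 99.99 for scrambled against untreated and 2.395 for the array labelled antisense against scrambled. With the arrays scaled to the spike-in controls, the medians of the lists of antigen presentation, B cell identity and histones turned positive against both controls, and that of cholesterol synthesis did so against untreated at 0.21, each below the common shift of 0.63 and 0.51. Control probe sets for 18S ribosomal RNA also differed on the array behind these lists. The 3-prime over 5-prime signal was 8.13 on the array labelled antisense, 4.48 on the scrambled and 1.72 on the untreated array. The 5-prime probe set read 640, 2434 and 4463, the first little above the floor of 595.9. The probe set for the middle of this RNA read 187, 2070 and 1009, so it was higher on the scrambled than on the untreated array. For actin and Gapdh, whose probe sets are among the brightest, the 3-prime over 5-prime ratio lay between 0.920 and 1.01 on the 3 arrays.

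**Figure D2:**
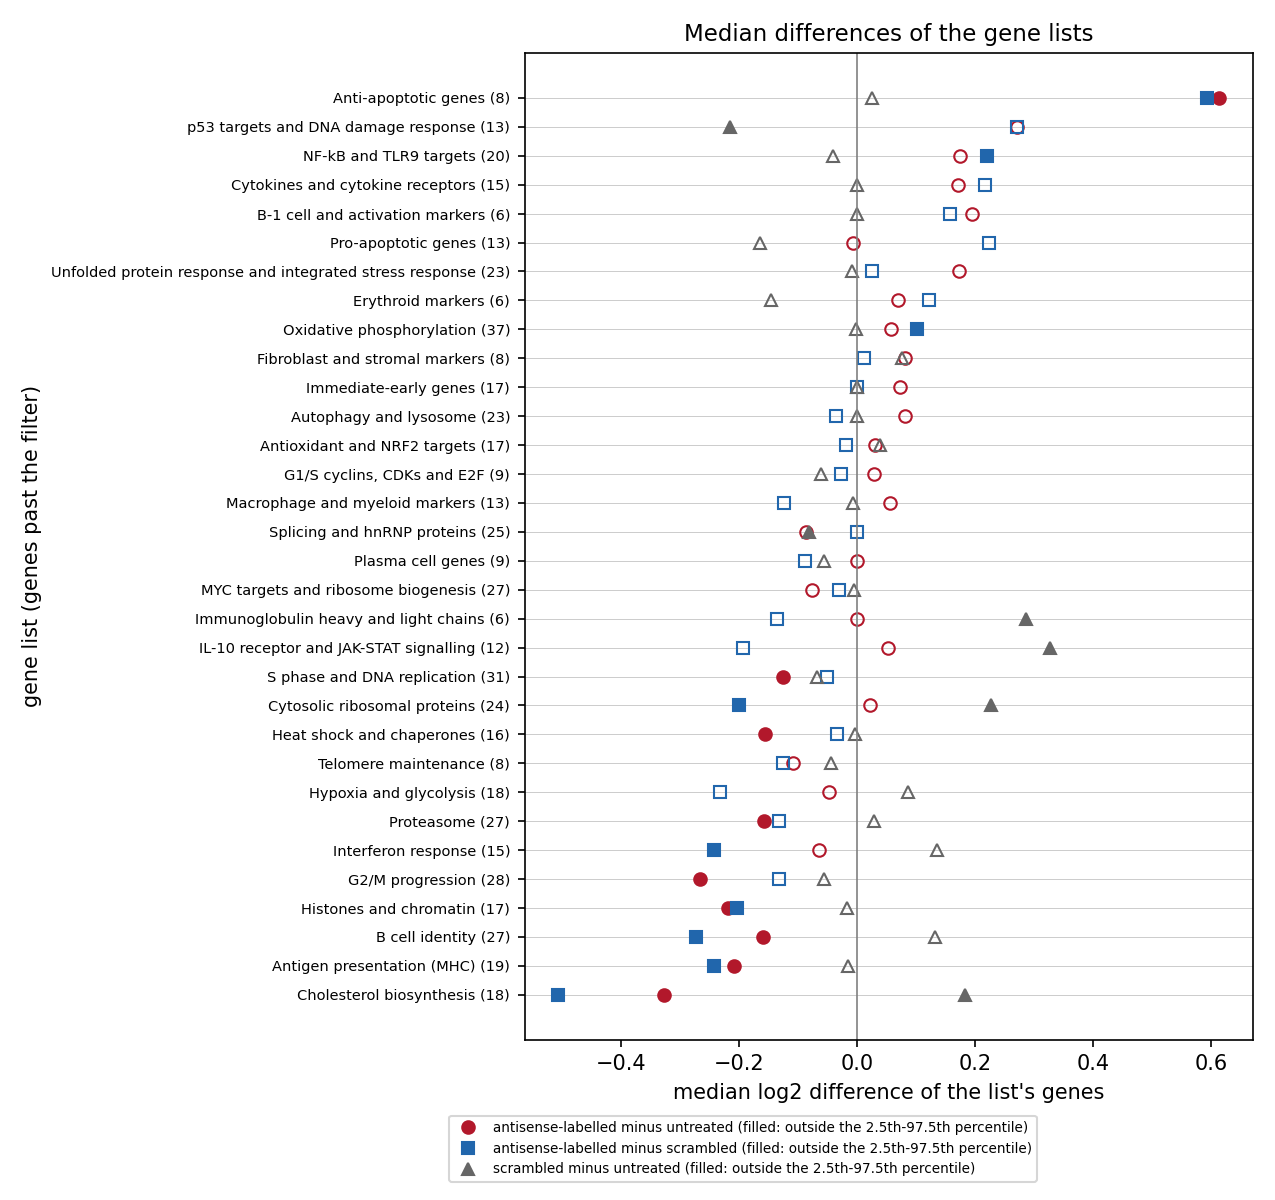
Median log2 difference of the genes of each fixed list past the filter, in the 3 comparisons, with filled symbols for medians outside the central 95% of matched random lists. The anti-apoptotic list lies highest at 0.61 and 0.59 and the cholesterol list lowest at -0.33 and -0.51, relative to the common level of each array; scaling to the spike-in controls moves them to 1.11 and 1.03 and to 0.21 and -0.01.

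**Figure D3:**
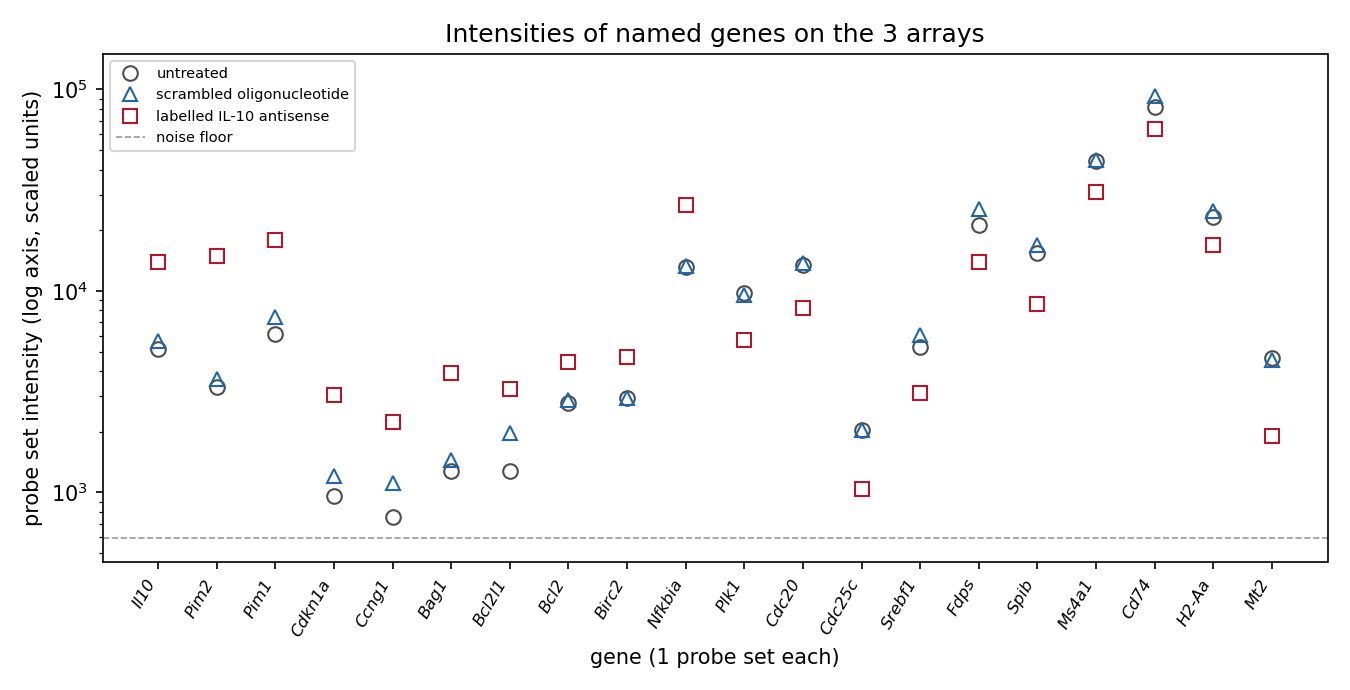
Intensities of 20 named genes on the 3 arrays on a log axis in scaled array units, 1 symbol per array and 1 probe set per gene, with the noise floor dashed. Il10, Pim2 and Nfkbia lie above both controls on the array labelled antisense and Spib, Plk1 and Mt2 below them.

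Against the untreated array alone, the array labelled antisense had 162 probe sets at least 2-fold higher and 135 at least 2-fold lower of 6127, 297 in all. Against the scrambled array, 196 were higher and 173 lower, 369 in all. Simulated unchanged arrays gave means of 153 and 150, and these run low, since the same simulation gave 153 for the scrambled against the untreated array, where 190 were counted. With scaling to the spike-in controls, 973 probe sets were higher and 39 lower against untreated, and 756 higher and 68 lower against scrambled. Egr1, an immediate-early transcription factor gene, differed by 1.53 against untreated and 0.95 against scrambled. Ier3, also an immediate-early gene, was 2.83-fold and 2.25-fold higher. Mt2, a metallothionein gene, differed by -1.29 and -1.25, and Tgfb1, a cytokine gene, by -0.94 and -0.66. Irf4, a transcription factor of plasma cells, read 24443 against 16268 and 15737.

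The scrambled and untreated arrays differed less than either did from the array labelled antisense, and with 1 array each the oligonucleotide cannot be separated from differences between arrays or cultures. Of 6127 probe sets, 104 were at least 2-fold higher and 86 lower on the scrambled array, 190 in all. Eif2ak1, a kinase that phosphorylates eIF2alpha, was 3.32-fold higher on the scrambled array and 4.02-fold higher on the array labelled antisense than on the untreated array, while a dimmer probe set of it, with a value at the floor, differed by 0.18 and -0.15. The kinase gene Map2k3 was higher by log2 differences of 1.32 and 1.42 in 1 probe set and differed by 0.22 and -0.13 in another. Psd, Cdcp1, Ckmt2, Zfp787 and Uchl1, a deubiquitinase gene, were higher on both oligonucleotide arrays by log2 differences of 1.23 to 1.78. Gstm1, a glutathione transferase gene, was higher by 2.67 on the scrambled array and 1.29 on the array labelled antisense. Ckmt2 and Gstm1 were read by family probe sets. The other probe sets of Ckmt2, Gstm1 and Zfp787 were at the floor on the 3 arrays. The difference of Uchl1 between the scrambled and untreated arrays lay just within the yardstick. Tomm20, a mitochondrial import receptor gene, read 3059 on the scrambled array and 3197 on the array labelled antisense against 6436 on the untreated array. Pola2, a DNA polymerase alpha subunit gene, differed by -1.11 and -1.10, in size slightly above its yardstick of 1.098. Fcgr2b, an inhibitory Fc receptor gene of B cells, differed by -1.13 and -0.97, both within its yardstick. Snai2, Junb, Hcn2, Banp and Zfp637 were also among the 8 lowest on both. The differences of Zfp637 lay within the yardstick. The other probe set of Junb was not lower in this way, and that of Hcn2 was at the floor on the 3 arrays. The simulated values for the counts that follow were drawn from the spread of the scrambled and untreated arrays themselves, so any oligonucleotide effect is part of them. In all, 29 probe sets were at least 2-fold higher on both oligonucleotide arrays than on the untreated array and 28 lower, against simulated means of 15.9, at most 26, and 24.0, at most 36. Independent lists would share 2.75 and 1.89. The number lower on both lay within the simulated range. This balance also turned with the processing, to 170 higher and 59 lower with the floor at the 40th percentile. It was 19 and 5 with the filter at the 70th percentile and 60 and 10 under spike-in scaling.

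The scrambled array stood apart from both others in 42 probe sets higher and 35 lower. Simulated means were 22.1, at most 34, and 16.1, at most 27. Both counts exceeded the simulated range, as did those of the array labelled antisense. They were 97 and 179 with the floor at the 40th percentile, 10 and 25 with the filter at the 70th percentile and 25 and 31 under spike-in scaling. Faf1, a gene of a Fas-binding protein, read 10359.8 against 1930.4 on the array labelled antisense and 3369 on the untreated array in a family probe set. Another probe set of Faf1 read 470 on the scrambled array, below the floor. Col4a2, a basement membrane collagen gene, was higher on the scrambled array too, as was Spin1, at least 2-fold in 1 of its 4 probe sets and less in another. Mafk, Apoa5 and Hoxa4 were lower there, and the other probe sets of Apoa5 and Hoxa4 were at the floor on the 3 arrays. Tbxas1, the thromboxane synthase gene, differed by -1.70 from untreated in 1 probe set and by 0.09 in another. Ribosomal protein genes were higher on the scrambled than on the untreated array, with a median of 0.23 over 24 genes and 22 of them higher. The median was -0.20 for the array labelled antisense against scrambled. Bright probe sets of other genes shared this: 83 equally bright ones had medians of 0.17 and -0.19. Over all 70 probe sets above an intensity of 100000, ribosomal ones included, the medians were 0.22 and -0.23. Without probe sets above 50000, 9 ribosomal genes were left, 4 of them with a value at the floor, and their differences of the array labelled antisense from scrambled ran from -1.55 to 0.64 with a median of 0.09. The IL-10 receptor and JAK-STAT list had a median of 0.33 between the scrambled and untreated arrays, and 0.05 and -0.19 for the array labelled antisense against untreated and scrambled. The 6 immunoglobulin genes had 0.29, 0.00 and -0.14 in these comparisons. Between the controls, 6 lists lay outside the central 95% of random lists, where 1.6 would be expected.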

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

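All tests in this part were chosen after the results were seen. Il10 RNA was higher, not lower, on the array labelled antisense. The error of a single probe set is argued against by the second Il10 probe set, whose smaller difference from a control was 0.678, above the yardstick of 0.56 at its level. The scaling of the arrays is argued against by the 300 probe sets nearest to Il10 in level, which share any scaling and had medians of -0.02 against untreated and 0.04 against scrambled, so the smaller excess of Il10 over them was 1.27 with a yardstick of 0.40. Exchanged array labels that hide a 2-fold loss of Il10 RNA against both controls are argued against by the lowest and middle arrays, which were 0.121 apart on the log2 scale whatever their labels. A response of Il10 RNA to the antisense oligonucleotide, an effect of this oligonucleotide unrelated to Il10, a difference between cultures and exchanged labels with a loss against only 1 control stay open and were not tested.

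Among control probe sets outside the comparisons, a probe set for B2 repeats, short interspersed elements that RNA polymerase III transcribes, read 27491 on the array labelled antisense against 14507 and 14534, a log2 difference of 0.920 from the nearer control. A probe set for B1 repeats, another family of short interspersed elements, read 32829 against 24912 and 19158, a difference of 0.398 from the nearer control. At this B1 probe set the scrambled array itself was 0.379 above the untreated array. The B2 and B1 probe sets were picked out because they exceeded the spread between the controls at their level. Whether the B2 difference is the error of a single probe set stays open, because the other B2 probe set, which went the other way at -0.301 against untreated and -0.68 against scrambled, is among the brightest, at 129642 and above on the 3 arrays, and whether signals this bright still follow the amount of RNA was not tested. No biological explanation was tested.

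Ribosomal protein genes were higher on the scrambled than on the untreated array, with a median of 0.23. Equally bright probe sets of other genes were higher too, by 0.173 in the median, and so were the bright bacterial CreX controls, by 0.25 and 0.32. A change of ribosomal protein genes alone is argued against, since their median excess over equally bright probe sets was 0.036, and 0.168 with 2 standard errors added. A signal difference of all bright probe sets may therefore account for the pattern, and a smaller share from the scrambled oligonucleotide stays untested.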

How the results depend on the processing

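No replicates exist, so nothing could be left out or split, and the alternatives below show dependence on processing alone. A floor at the 10th percentile was not run, because that percentile is negative. Scaling to spike-in controls, the floor of 4 robust standard deviations and removal of the brightest probe sets were chosen after seeing the data. Counts are given in the order antisense-labelled against untreated, against scrambled, scrambled against untreated, higher and lower than both controls in the array labelled antisense, and higher and lower with both oligonucleotides. The main counts were 297, 369, 190, 83, 65, 29 and 28. With the floor at the 40th percentile they were 786, 911, 607, 125, 295, 170 and 59. With the filter at the 70th percentile they were 138, 181, 86, 32, 43, 19 and 5, fewer by construction. At 1.5-fold they were 1080, 1231, 788, 332, 258, 134 and 133, and at 3-fold 53, 71, 33, 16, 6, 4 and 5. With the floor at 4 robust standard deviations they were 95, 129, 49, 37, 15, 4 and 6. Without suffixed probe sets the counts with both oligonucleotides were 18 and 18. Under spike-in scaling, 1012, 824, 512, 19, 60 and 10 were counted in the comparisons other than scrambled against untreated. Of the probe sets apart from both controls, 56.1% were higher in the main setting, 29.8% with the 40th percentile floor, 42.7% with the 70th percentile filter, 72.7% at 3-fold, 71.2% with the floor of 4 robust standard deviations and 96.4% under spike-in scaling.

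The Il10 difference was 2.06 against untreated and 1.82 against scrambled under spike-in scaling, and stayed within its yardstick of the main 1.43 and 1.31 under the other settings run. That scaling adds 0.63, 0.51 and 0.12 to values above the floor by construction, Il10 included, and reversed 14 of the list medians that lay outside the central 95% in the main setting; medians inside it were not counted. Against untreated they became 0.42 for antigen presentation, 0.45 for B cell identity, 0.21 for cholesterol synthesis, 0.36 for G2/M, 0.47 for heat shock, 0.41 for histones, 0.47 for proteasome and 0.50 for DNA replication. Against scrambled they became 0.18 for antigen presentation, 0.21 for B cell identity, 0.31 for ribosomal proteins, 0.35 for histones and 0.18 for interferon response, and between the controls 0.037 for splicing. Without the brightest probe sets the ribosomal median against scrambled was 0.093, over 9 genes of which 4 had a value at the floor. The cause of other moves was not tested. Signal over background limits the counts: 46 of the 83 higher and 27 of the 65 lower probe sets had a value at the floor. Of 11 alternatives, the anti-apoptotic, antigen presentation, B cell identity and cholesterol lists were apart in 10, 10, 10 and 11, the histone list in 3, and the proteasome, NF-kB and p53 lists, not apart in the main setting, in 5, 2 and 1. These are not independent checks, since several alternatives hardly alter a list. The anti-apoptotic median against untreated was 0.62 as deposited and 0.61 with coarser matching or without the brightest probe sets. Under spike-in scaling, the antigen presentation and B cell lists counted as apart because they ranked below random lists, though their medians were positive. The values as deposited, no expression filter and removal of the brightest probe sets left the counts nearly or exactly as they were, since they alter almost no tested value. Without the filter no other outcome was possible for the counts, since every added probe set has all values at the floor.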

Other observations

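Further lists were not apart from both controls on the array labelled antisense. Of 16 heat shock and chaperone genes, 7 were lower than both controls and 6 higher, with medians of -0.16 against untreated and -0.03 against scrambled. Hspa4 read 4297 against 8759 on the scrambled and 8541 on the untreated array in 1 probe set, but differed by 0.07 and 0.16 in another, by -0.70 and 0.00 in another, and by -1.20 and -0.43 in a dimmer one with a value at the floor. Hspa8 read 29367 against 39422 and 43111, while Hspe1, a mitochondrial chaperonin gene, differed by 0.69 and 0.31. Of 18 genes of hypoxia and glycolysis, 9 were lower than both and 5 higher, with medians of -0.05 and -0.23. Tpi1, triosephosphate isomerase, differed by -0.83 and -0.78. Of 23 genes of the unfolded protein and integrated stress responses, 10 were higher and 8 lower than both, with medians of 0.17 and 0.02. The chaperone gene Hspa5 differed by -0.67 and -0.49, and Ddit3, a stress transcription factor gene, by 0.94 and 0.09. Of 15 interferon response genes, 8 were lower than both and 5 higher, with medians of -0.06 and -0.24. Of 37 genes of oxidative phosphorylation, 19 were higher than both and 11 lower, with medians of 0.06 and 0.10, and Cox6c differed by 0.35 and 0.53. Of 17 antioxidant genes, 4 were higher and 4 lower than both, with medians of 0.03 and -0.02.

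The remaining lists were not apart either. Medians against untreated and scrambled were 0.17 and 0.22 for 15 cytokine and receptor genes, 0.19 and 0.16 for 6 B-1 cell and activation markers, 0.07 and 0.00 for 17 immediate-early genes, and 0.00 and -0.09 for 9 plasma cell genes. They were 0.03 and -0.03 for 9 G1/S genes, -0.08 and -0.03 for 27 MYC target and ribosome biogenesis genes, -0.09 and 0.00 for 25 splicing genes, -0.11 and -0.13 for 8 telomere genes and 0.08 and -0.04 for 23 autophagy and lysosome genes. Markers of other cell types had medians of 0.05 and -0.12 for 13 macrophage genes, 0.08 and 0.01 for 8 stromal genes and 0.07 and 0.12 for 6 erythroid genes. Of the T and NK cell markers, 2 passed the filter, too few for a median.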
